A study of Mus musculus with 10 samples.

How the data were processed

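RNA-seq was measured in 10 mouse samples, 5 of CD11b-positive cells sorted from brain and 5 of hemi brains. Per the labels' protocols, RNA was extracted with Qiazol and a miRNeasy column, messenger RNA was selected on poly-T beads, and cDNA was primed with random hexamers after fragmentation. The labels give 1 batch value for all samples. Per the submitters' processing notes, the tools CASAVA, HISAT2 2.2.1 and featureCounts 2.0 and the genome build GRCm39 (mm39) were used, with no role or order stated. The strand setting, the rule for reads that map to several places and the annotation release are not given in the sources used here. The authors deposited 1 table of raw counts per gene, with no normalization, for 56748 genes, of which 21970 are protein-coding and 19936 had 0 counts in all libraries. All 10 value columns were mapped to a sample (0 were not). Of the genes, 0 lacked an identifier, and gene symbols, coordinates (1-based), biotypes and gene lengths were taken from the same table per the file headers. Because the strand setting is unknown, reads of overlapping and antisense genes may be mixed, and genes with near-identical copies (Hspa1a and Hspa1b, Lilrb4a, the H2 and Hba genes, and mitochondrial genes with nuclear copies such as mt-Co2 and mt-Co3) are uncertain.

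Total counts per library were 25087489 to 28514509 in microglia and 25845049 to 34709215 in bulk brain, so that 3 counts, the limit that a count of 0 allows, correspond to 0.086 to 0.12 CPM in a single library. Folds against a group with 0 counts use a floor of 3 counts over the group, and genes with 1 to 3 counts have an exact Poisson interval. Medians of lists were also taken with zero-count genes at their bound, and both are given where they differ. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers. Replicates of a group differed by more than counting noise (chi-square per degree of freedom of at least 5.64), which library preparation alone may give. Each library was counted as a sample, as the labels list them.

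Genes were kept by edgeR's filterByExpr by group (18969 genes), scaled by TMM, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with group as the only term and all 10 libraries in the fit. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM were computed from the deposited counts with TMM-scaled library totals, and log2 fold changes are microglia minus bulk brain. The SE of a log2 difference is its size divided by the square root of the test's F statistic, not a fitted standard error. The 40 gene lists (16 main and 24 other, with 1190 memberships of 1144 distinct genes, so that some genes stood in more than 1 list), the tests and the alternatives were fixed before the data were examined, and 5 listed symbols were not found in the table. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Summed list levels and shares of counts were compared by exact two-sided permutation tests over the 252 splits of 5 against 5, whose smallest p is 0.0079, and adjusted over the 40 list levels and over the 6 shares. The gene length of the table and the GC content of the longest transcript of each gene in a GENCODE vM21 annotation, matched by gene identifier for 99.9% of the genes, were used for checks within bulk brain. No coordinates of that annotation, which is of another build, were used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for levels, tests and plots.

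The named genes were fixed by rule: 11 chosen in advance, the 5 largest rises and the 5 largest falls among coding genes past the threshold whose groups did not overlap and with at least 100 CPM in the higher group, and for each main list the member with the largest change in the list's prevailing direction and in the other, with at least 5 CPM. This gave 45 distinct genes, not all of which are named in the text. Other genes named in the text were chosen after their values were seen. The test was tested on simulated data, with counts for both groups drawn from the mean profile of bulk brain at the samples' library sizes. After the low-count filter 17519 genes were tested, of which 67, 67 and 66 had been changed by 1.5-fold, 2-fold and 4-fold. In that simulation, 4.48% of 1.5-fold, 32.8% of 2-fold and 92.4% of 4-fold changes were recovered, and 5.49% of calls were false. Far fewer genes changed there than between the real groups, which makes the adjusted threshold stricter. These shares therefore do not give the recovery in the real comparison. The alternatives were other scalings (median-of-ratios size factors, library size, upper quartile), other low-count filters, DESeq2 1.42.0, limma-voom, a test against a 2-fold change, the replicate number as a block, thinning to the smallest library total, coding genes only, no mitochondrial genes, and leaving out each replicate. Fits with bulk brain replicates 3 to 5 alone, and with replicates 1 and 2 alone, were added after seeing the data.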

Results

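The transcriptome of microglia, the resident macrophages of the brain, was compared with that of brain tissue from which no cell type had been isolated. Poly-A selected RNA-seq libraries were counted for 5 samples of CD11b-positive cells sorted from mouse brain, at 400000 cells per sample, and for 5 samples of hemi brains, called bulk brain here. All mice were young C57BL/6 males. The series title concerns synaptic proteins that accumulate in microglia with age, and the comparison addresses which synaptic transcripts microglia themselves hold. No aged samples and no protein measurements were analysed here. Microglia libraries held 25087489 to 28514509 counts and bulk brain libraries 25845049 to 34709215. The labels do not say that the 5 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

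Itgam, P2ry12 and Tmem119, which mark microglia, were 107-fold to 175-fold higher in the sorted cells than in bulk brain. Itgam, which encodes CD11b, the antigen used for the sort (ENSMUSG00000030786, chromosome 7, 127661812 to 127717663, plus strand, GRCm39), stood at 498 ± 18 CPM (read counts scaled by library total and composition; SD, n = 5) in microglia and 4.65 ± 1.24 CPM in bulk brain (n = 5), a log2 difference of 6.74 ± 0.21 (SE; edgeR quasi-likelihood test, adjusted p = 9.6e-11). The purinergic receptor gene P2ry12 reached 3648 ± 135 CPM against 20.8 ± 4.01 CPM, and the microglial surface protein gene Tmem119 reached 2435 ± 88.0 CPM against 16.2 ± 5.12 CPM. All 25 genes of a list of homeostatic microglia genes were higher in microglia, with a median log2 difference of 6.82, and the G-protein-coupled receptor gene Gpr34 had the largest (7.55 ± 0.13 SE, edgeR adjusted p = 2.8e-12). All 19 myeloid transcription factor genes were higher too (median 5.47), led by Runx1 at 146 ± 5.66 CPM against 0.792 ± 0.268 CPM. Adjusted over the list alone, the counts were the same in both lists, at 25 and 19. Both lists stood above the other genes by camera, with adjusted p = 7.5e-18 and 8.8e-12, and 0.013 and 0.0021 with an estimated correlation.

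Across the 18969 genes tested, 7048 were higher and 8320 lower in microglia at an adjusted p under 0.05 (edgeR quasi-likelihood test). Of these, 5279 were at least 2-fold higher and 6983 at least 2-fold lower. The median log2 difference of all genes was -0.14, which moved to -0.31 with median-of-ratios size factors, to -0.33 with library size alone and to -0.07 with upper-quartile scaling, so that small differences depend on the scaling. With no filter on low counts, the genes at least 2-fold lower numbered 10887. The number of genes higher in microglia was 7621 and of genes lower 9534 when bulk brain replicates 3 to 5 alone were used, a choice made after seeing that replicates 1 and 2 stood apart.

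**Figure D1:**
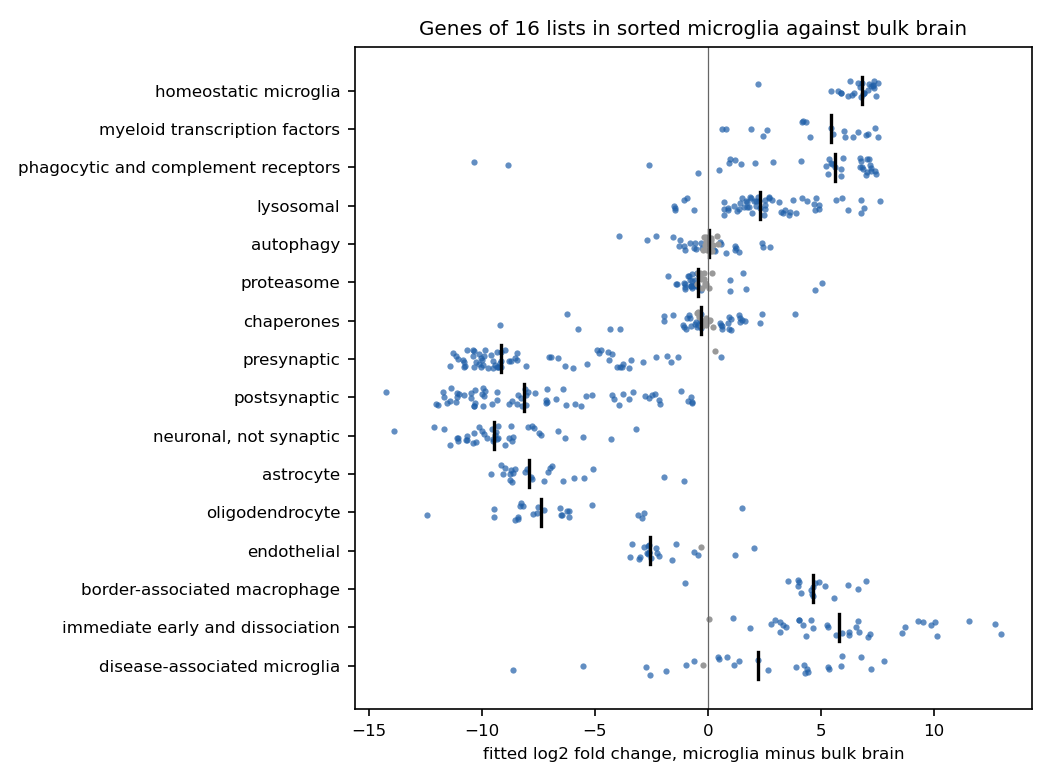
Each point is a gene of 1 of 16 lists, placed by its fitted log2 fold change (microglia minus bulk brain, 5 libraries each); blue points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Homeostatic microglia genes lie to the right (median 6.82) and presynaptic genes to the left (median -9.17), and points of genes with 0 counts in a group depend on the prior count of the fit.

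Phagocytic receptor genes and lysosomal genes were mostly higher in microglia. Of 35 phagocytic and complement receptor genes, 31 were higher and 4 lower (median log2 difference 5.62), with the complement receptor gene C3ar1 at 295 ± 11.9 CPM against 1.71 ± 0.586 CPM. The 4 lower genes were the adhesion receptor gene Adgrb1 (log2 difference -10.36), the receptor kinase gene Tyro3 (-8.84), Mfge8, which encodes a secreted bridging protein (-2.60), and Cd47 (-0.42). Of 59 lysosomal genes tested, 53 were higher and 6 lower (median 2.30). The metal ion transporter gene Slc11a1 rose most (7.62 ± 0.14 SE, edgeR adjusted p = 3.2e-12), and the cysteine protease gene Ctss stood at a log2 difference of 6.78. Gaa, the lysosomal acid glucosidase gene, was lower, at 136 ± 7.93 CPM against 377 ± 55.0 CPM. Adjusted over the list alone, the same counts passed, 31 and 4 for receptors and 53 and 6 for lysosomal genes. Both lists stood above the other genes by camera (adjusted p = 5.1e-12 and 8.8e-16), and with an estimated correlation the adjusted p was 0.0011 and 0.042.

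Autophagy, proteasome and chaperone genes moved both ways, and none of the 3 lists passed camera's threshold. Of 44 autophagy genes, 12 were higher, 14 lower and 18 not past the threshold (camera adjusted p = 0.56), and adjusted over the list alone 11 were higher and 14 lower. Against bulk brain replicates 3 to 5 alone, 14 were higher, 22 lower and 8 not past the threshold (camera adjusted p = 0.88). The transcription factor gene Tfe3 was higher (210 ± 14.3 CPM against 31.3 ± 2.36 CPM) and the ATG8 family gene Gabarapl1 lower (26.8 ± 2.44 CPM against 405 ± 111 CPM). The median autophagy gene had a log2 difference of 0.07 while the mean was -0.03, and the median was -0.11 with median-of-ratios size factors and -0.12 with library size alone. Of 43 proteasome genes, 6 were higher and 23 lower (median -0.45, camera adjusted p = 0.80), counts that were the same over the list alone. The immunoproteasome subunit gene Psmb9 was higher (45.6 ± 1.36 CPM against 1.36 ± 0.367 CPM) and the regulatory ATPase gene Psmc5 lower (50.4 ± 3.74 CPM against 173 ± 75.6 CPM). Of 52 chaperone genes, 17 were higher and 23 lower (camera adjusted p = 0.87), again the same over the list alone, and camera's direction was up although the median was -0.29 and the mean -0.45. The co-chaperone gene Dnajb1 was higher (653 ± 121 CPM against 45.6 ± 8.26 CPM), and Dnajc6, which encodes the uncoating factor auxilin, was lower (0.570 ± 0.357 CPM against 335 ± 80.5 CPM). With bulk brain replicates 1 and 2 alone, chosen after seeing the data, the proteasome list stood below the other genes (median -0.93, camera adjusted p = 8.5e-04 with the preset correlation). With an estimated correlation against all bulk brain libraries its adjusted p was 0.96.

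Synaptic transcripts were far lower in sorted microglia than in tissue, but not to the same degree for every gene. Snap25, a presynaptic membrane fusion gene (ENSMUSG00000027273, chromosome 2, 136555373 to 136624348, plus strand, GRCm39), stood at 2.39 ± 0.379 CPM in microglia and 1746 ± 48.9 CPM in bulk brain (log2 difference -9.51 ± 0.16 SE, edgeR adjusted p = 2.8e-12). The synaptic vesicle gene Syp stood at 1.63 ± 0.502 CPM against 730 ± 179 CPM. Of 67 presynaptic genes tested, 65 were lower, 1 was higher and 1 did not pass the threshold (median -9.17, or -9.16 with zero-count genes at their bound). Kcna1, a potassium channel gene, stood at 0.0318 ± 0.0711 CPM against 98.4 ± 77.0 CPM, with all 4 of its microglia counts in replicate 1. Its bulk brain level was 23.9 and 5.22 CPM in replicates 1 and 2 and 145 to 162 CPM in replicates 3 to 5, and its log2 difference of -11.42 ranged from -14.52 to -8.76 over the alternatives. The scaffold gene Cask (ENSMUSG00000031012, chromosome X, 13383319 to 13717606, minus strand) was the member that was higher, at 122 ± 3.16 CPM against 82.4 ± 17.7 CPM (log2 difference 0.56 ± 0.14 SE, edgeR adjusted p = 0.0027), a call lost without bulk brain replicate 1 (log2 difference 0.37, adjusted p = 0.053; over all alternatives 0.20 to 0.86 and 7.9e-06 to 0.053). All 66 postsynaptic genes were lower (median -8.15). The glutamate receptor gene Grik2 had 0 counts in the 5 microglia libraries and 83.3 ± 26.7 CPM in bulk brain, at least 3461-fold lower against a floor of 3 counts over the group. Dlg4, which encodes the postsynaptic scaffold PSD-95 (ENSMUSG00000020886, chromosome 11, 69907768 to 69938348, plus strand), kept 49.6 ± 3.35 CPM against 493 ± 15.1 CPM (-3.31 ± 0.09 SE, edgeR adjusted p = 2.4e-11). The counts were the same adjusted over the list alone, 65 and 66 lower. Camera gave adjusted p = 7.8e-20 for the presynaptic and 2.3e-18 for the postsynaptic list, and 0.027 for both with an estimated correlation.

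Summed over their members, presynaptic transcripts in microglia amounted to 4.46% ± 0.18 of the bulk brain level (SD, n = 5) and postsynaptic transcripts to 7.06% ± 0.33 (n = 5). Neuronal genes outside the synapse amounted to 0.671% ± 0.157 (n = 5), with all 40 genes lower (median -9.47, camera adjusted p = 8.5e-17, and 0.0030 with an estimated correlation), also 40 when adjusted over the list alone. Each of these sums was below bulk brain in all 5 libraries (exact two-sided permutation test, p = 0.0079, the smallest that 5 against 5 can give, adjusted p = 0.0088). The difference between the synaptic and the neuronal residue was not tested at the level of sums. Taken as the median over members, the residue was 0.201% for presynaptic, 0.369% for postsynaptic and 0.133% for other neuronal genes, and 10 of 133 synaptic genes held 66.5% of the synaptic CPM in microglia. Of these 133 genes, 88 lay at or below the 90th percentile of the other neuronal genes (1.03%), Snap25 and Syp among them, and Dlg4 and Cask lay above it. The neuronal nuclear protein gene Rbfox3 stood at 0.831 ± 0.579 CPM against 209 ± 10.4 CPM. The potassium channel gene Kcnc1 had 2 counts over the microglia libraries, both in replicate 2, a ratio of 19220 (95% counting interval 5321 to 158707).

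**Figure D2:**
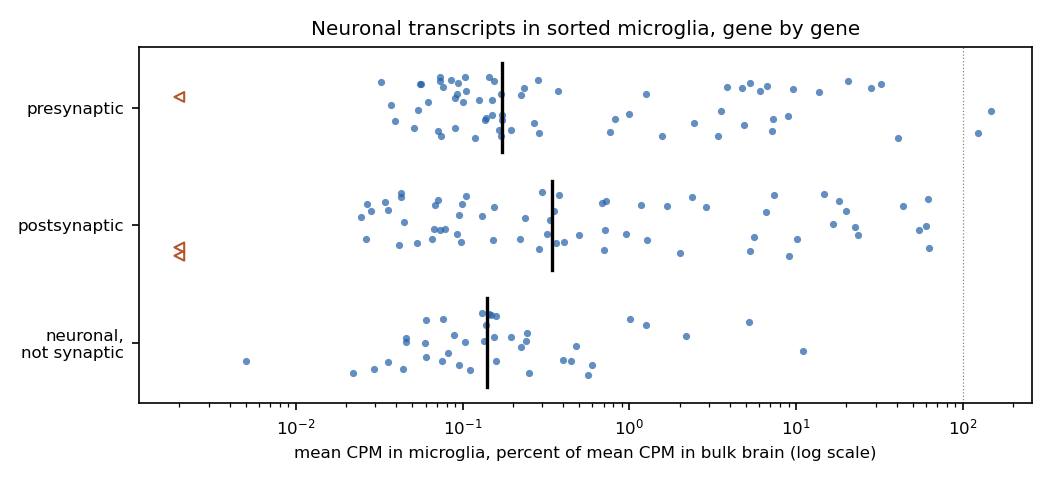
Each point is a gene of the presynaptic, postsynaptic or other neuronal list, placed by its mean CPM in microglia as a percent of its mean CPM in bulk brain (log axis, 5 libraries per group); black bars are medians and open triangles at the left edge are genes with 0 counts in microglia. Cask lies at 148% and Snap25 at 0.137%, and the dotted line marks equal levels at 100%.

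Transcripts of other brain cell classes were low in the sorted cells. All 24 astrocyte genes were lower (median -7.92), with the intermediate filament gene Gfap at 0.563 ± 0.254 CPM against 248 ± 51.7 CPM. Cyp4f14 had 1 count over the microglia libraries, a ratio of 1183 (95% counting interval 212 to 46719). Of 24 oligodendrocyte genes, 23 were lower (median -7.38). The myelin gene Mbp stood at 76.8 ± 23 CPM against 2668 ± 488 CPM, and the gap junction gene Gjb1, with 0 counts in microglia, was at least 990-fold lower. The transferrin gene Trf was the member that was higher, at 1613 ± 52.9 CPM against 572 ± 136 CPM. Of 22 endothelial genes, 19 were lower and 2 higher (median -2.56), with the tight junction gene Cldn5 at 6.85 ± 2.60 CPM against 48.7 ± 33.4 CPM (106 CPM in bulk brain replicate 2) and Itm2a at 5.33 ± 2.37 CPM against 57.7 ± 13.6 CPM. Abcg2, a drug efflux transporter gene, was higher (72.9 ± 3.49 CPM against 17.5 ± 2.01 CPM), as was Pecam1 (log2 difference 1.19). Summed levels in microglia were 3.09% ± 0.27 of bulk brain for astrocyte, 21.7% ± 0.89 for oligodendrocyte and 52.1% ± 3.59 for endothelial genes (SD, n = 5 libraries; exact permutation adjusted p = 0.0088 each). As medians over members the levels were 0.425%, 0.598% and 19.7%, and Trf held 1613 of the 1831 CPM of oligodendrocyte genes in microglia. Counts adjusted over the lists alone were 24, 23 and 19 lower. Camera gave adjusted p = 1.5e-08 for astrocyte, 2.3e-09 for oligodendrocyte and 0.022 for endothelial genes. With an estimated correlation the adjusted p was 0.027 for astrocyte, 0.054 for oligodendrocyte and 0.25 for endothelial genes, and the endothelial call was also lost without bulk brain replicate 2 (adjusted p = 0.14) and against replicates 3 to 5 alone (0.47).

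**Figure D3:**
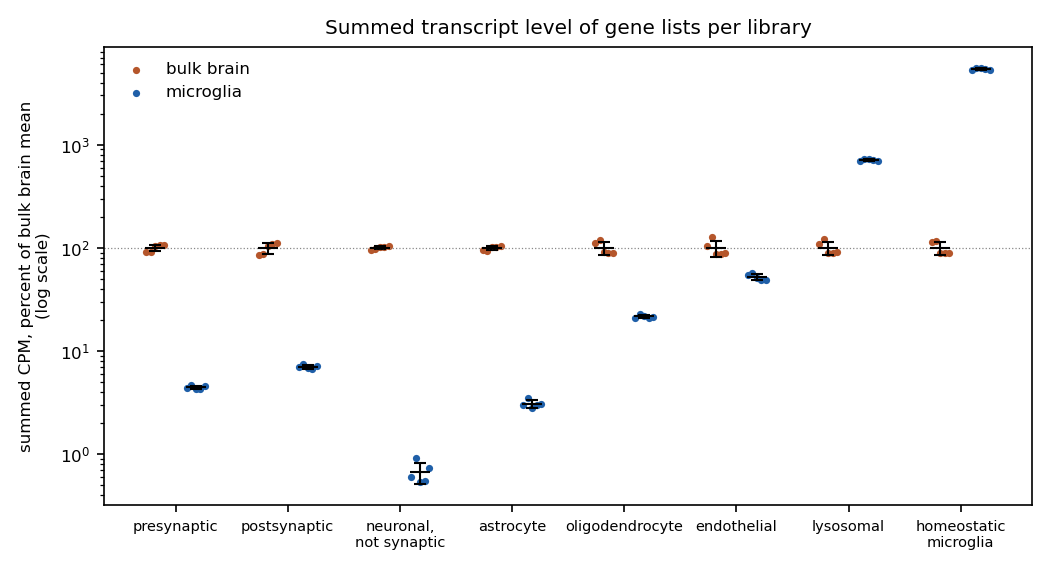
Points are libraries, placed by the summed CPM of a gene list as a percent of the bulk brain mean (log axis), with the mean and SD of 5 libraries per group. Microglia libraries lie near 4.46% of bulk brain for presynaptic, 0.671% for other neuronal and 21.7% for oligodendrocyte genes, of which Trf held 1613 of 1831 CPM, and near 717% for lysosomal genes.

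Genes listed for border-associated macrophages, for the immediate early and dissociation response and for disease-associated microglia were mostly higher in the sorted cells. Of 17 genes of border-associated macrophages, which line brain vessels and meninges and also carry CD11b, 16 were higher (median 4.64, camera adjusted p = 1.7e-06, and 0.046 with an estimated correlation). The lectin gene Siglec1 stood at 27.9 ± 3.54 CPM against 0.219 ± 0.220 CPM, and the scavenger receptor gene Colec12 was lower (7.22 ± 1.61 CPM against 14.4 ± 2.14 CPM). Of 36 immediate early and dissociation genes, 35 were higher and 1, Egr3, did not pass the threshold at a log2 difference of 0.05 (median 5.81, camera adjusted p = 1.0e-18, and 0.027 with an estimated correlation). Among coding genes with at least 100 CPM in microglia, the largest fitted rises were in the chemokine gene Ccl3, with 179 ± 15.7 CPM in microglia and 3 counts over the 5 bulk brain libraries (ratio 10085, 95% counting interval 3451 to 48902), Rgs1, a regulator of G-protein signalling (352 ± 54.6 CPM against 0.0694 ± 0.0787 CPM), Ccl4 (281 ± 26.2 CPM against 0.0894 ± 0.0644 CPM), the stress-induced transcription factor gene Atf3 (1433 ± 175 CPM against 1.26 ± 0.324 CPM) and the mRNA decay factor gene Zfp36 (3084 ± 233 CPM against 3.27 ± 0.646 CPM). Ccl3, Ccl4, Atf3 and Zfp36 belong to the immediate early and dissociation list, and bulk brain held these 4 and 6 other genes of the list at under 0.533% of the microglial level, the lowest such value among the 25 homeostatic genes. Of 27 disease-associated microglia genes tested, 19 were higher and 7 lower (median 2.21, camera adjusted p = 3.5e-04, and adjusted p = 0.092 with an estimated correlation). The median was below that of homeostatic genes (6.82), and a comparison of microglia with tissue cannot show activation. Lilrb4a, an inhibitory receptor gene with a close paralog that may share its reads, stood at 41.7 ± 5.17 CPM against 0.190 ± 0.155 CPM, and the fatty acid binding protein gene Fabp5 was lower (1.53 ± 0.547 CPM against 70.2 ± 27.3 CPM). Counts adjusted over the lists alone were 16, 35 and 19 higher.

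Among coding genes with at least 100 CPM in bulk brain, the largest fitted falls included those of Lamp5, which had 0 counts in microglia and was at least 4851-fold lower, of Kcnc1, of the receptor gene Gpr158, with 1 count over the microglia libraries (ratio 20730, 95% counting interval 3721 to 818770), and of Tmem130 (0.0312 ± 0.0325 CPM against 283 ± 48.8 CPM). Of the 40 lists tested, 32 passed camera's threshold with its preset correlation and 18 with an estimated correlation. With the preset correlation, 33 of 100 splits of the 10 libraries, the real one included, called 32 or more lists, where each of the other splits still put 3 or 4 microglia libraries on 1 side.

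The make-up of the libraries differed between the groups. Mitochondrially encoded genes took 0.625% ± 0.035 of the counts in microglia and 3.15% ± 0.59 in bulk brain (SD, n = 5 each; exact two-sided permutation test, p = 0.0079, adjusted p = 0.012). The 20 most abundant genes took 8.78% ± 0.064 in microglia and 6.20% ± 0.31 in bulk brain (exact permutation p = 0.0079, adjusted p = 0.012). Cytosolic ribosomal protein genes took 1.14% ± 0.020 and 1.11% ± 0.59, which did not differ detectably beyond the spread of bulk brain (exact permutation p = 1).

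The bulk brain libraries fell apart into replicates 1 and 2 and replicates 3 to 5. The first principal component within bulk brain held 73.7% of the variance, with scores of 0.32 and 0.73 for replicates 1 and 2 and -0.34 to -0.36 for the rest. The biological coefficient of variation was 32.9% over the 5 bulk brain libraries and 12.7% over microglia. Within bulk brain it was 22.6% over replicates 1 and 2 and 6.55% over replicates 3 to 5. Replicates 1 and 2 thus also differed from each other, with a chi-square per degree of freedom of 50.1, against 5.64 to 8.13 among replicates 3 to 5. The log2 difference between replicates 1 and 2 and replicates 3 to 5 followed gene length across 13867 coding genes (Spearman rho = -0.687 across genes, which are not independent replicates). Ribosomal protein genes moved with this difference. Against all bulk brain libraries 13 of 81 were higher and 3 lower (median 0.16, or -0.03 with library size alone, camera adjusted p = 0.13). With the replicate number as a block the median was 0.35 (adjusted p = 0.030). Against replicates 3 to 5 alone 71 of 82 were higher (median 0.67, camera adjusted p = 1.3e-04), without replicate 2 the median was 0.42 (adjusted p = 0.040), and against replicates 1 and 2 alone the median was -0.56 (adjusted p = 0.035). These calls rest on the preset correlation, and the adjusted p against all bulk brain libraries was 0.86 with an estimated correlation. The synaptic lists kept their direction in both choices, with 66 of 67 presynaptic and 66 of 66 postsynaptic genes lower against replicates 3 to 5.

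**Figure D4:**
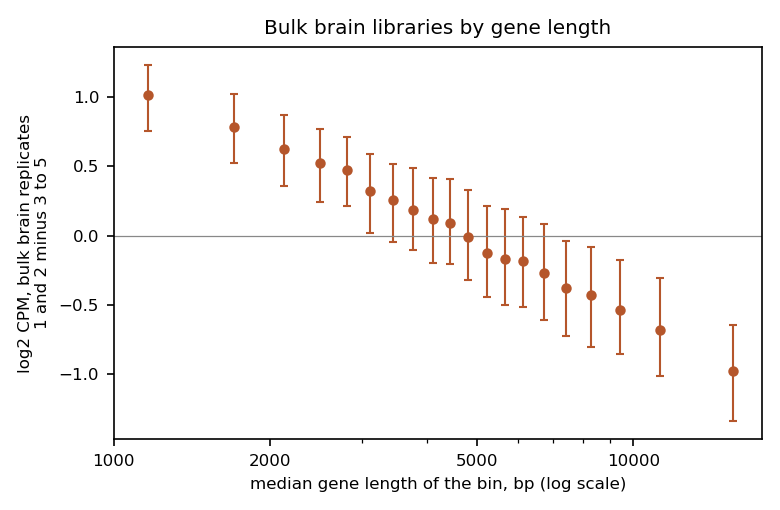
Points are 20 bins of coding genes ordered by gene length (log axis, bp), placed by the median log2 CPM difference between bulk brain replicates 1 and 2 and replicates 3 to 5, with bars that span the quartiles. The median goes from 1.01 in the bin of shortest genes to -0.98 in the bin of longest genes.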

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

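The tests of the patterns weighed here, except the count of lists with an estimated correlation, were chosen after the results were seen. Of 180 groups of 5 libraries checked, 17 held a library far from the others, where chance alone would give about 9, but 4 of the 17 were genes whose 1 to 4 microglia counts all lay in 1 library, which fixes the outcome. In microglia, replicate 2 was highest for summed V-ATPase genes (2517 CPM, others 2393 to 2426) and for cell cycle genes (406.2 CPM, others 375 to 381). Replicate 5 was lowest for chemokine and cytokine genes (1475 CPM, others 1587 to 1608) and for Tmem119 (2281 CPM, others 2439 to 2493). Replicate 3 was highest for interferon-stimulated genes (1287 CPM, others 870 to 983), and replicate 1 had the lowest share of processed pseudogenes (0.264%, others 0.276 to 0.278%). A single library held all counts of Kcnc1 (0.0776 CPM, replicate 2), Gpr158 (0.0417 CPM, replicate 5), Kcna1 (0.159 CPM, replicate 1) and Cyp4f14 (0.0398 CPM, replicate 4). In bulk brain, replicate 2 was highest for autophagy genes (4192 CPM, others 3857 to 3923), inhibitory neuron genes (2351 CPM, others 2127 to 2184) and Cldn5 (106 CPM, others 26.7 to 48.6), and lowest for monocyte genes (102 CPM, others 152 to 168) and Abcg2 (13.9 CPM, others 17.9 to 18.9). Replicate 5 was highest in the share of the most abundant genes (6.74%, others 5.95 to 6.10%) and for Rbfox3 (228 CPM, others 204 to 206).

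Bulk brain replicates 1 and 2 stood apart from replicates 3 to 5. Gene length may account for part of this: the log2 difference fell with length across 13867 genes (rho = -0.687), from 1.01 in genes up to 1467 bp to -0.98 in genes of at least 12763 bp, and rose with GC content (rho = 0.381). The table's gene length as the whole cause is argued against by ribosomal protein genes, whose median went from 1.21 to 0.484 ± 0.047 (bootstrap SE over 80 genes) when its trend was removed. This SE treats the genes as independent, though the list's estimated inter-gene correlation was 0.94, and does not measure the spread between libraries. The table's gene length can count the whole span of a gene, as for Rgs1 (6947 bp), and is not the length of the transcripts. Transcript length as the whole cause therefore stays open. A different mix of broad cell classes as the whole cause is argued against by the trend within 171 neuronal and synaptic genes (rho = -0.767), which such a mix would move together. RNA integrity, library preparation and a difference between the animals or the dissection stay open, as nothing in the labels separates these libraries and no biological explanation other than the mix of cell classes was tested.

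Among 100 splits of the 10 libraries, only the real split (1) gave as many genes higher (7048), lower (8320), at least 2-fold higher (5279) or at least 2-fold lower (6983), and the highest of the other splits was 0 for each. With camera's preset correlation, 33 of 100 splits, the real one included, gave 32 or more lists, and the highest of the others gave 34. With an estimated correlation, 1 split, the real one, gave 18 lists and the highest of the others gave 0. Every other split mixed 3 or 4 microglia libraries with bulk brain, which carries the real difference into both the contrast and the spread within its sides. These splits are therefore a poor reference for no change and decide nothing about chance, for genes as for lists.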

How the results depend on the processing

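The alternatives were set before the data were examined, except the fits with bulk brain replicates 3 to 5 or 1 and 2 alone. Under the scaling, filter, tool, depth, block and leave-one-out alternatives, 0 genes were called in opposite directions. The genes higher numbered 5756 to 7684 and the genes lower 6837 to 12197, and a test against a 2-fold change called 4450 and 6364. Genes at least 2-fold lower numbered 10887 with no low-count filter, where 36812 genes were tested instead of 18969. With an estimated inter-gene correlation 18 lists were called, and with bulk brain replicates 3 to 5 alone, 28. Leaving out a replicate gave 6677 to 7127 genes higher, 8575 to 9033 lower, 5058 to 5344 at least 2-fold higher, 7304 to 7446 at least 2-fold lower and 31 to 33 lists. Against bulk brain replicates 3 to 5 alone, the share of ribosomal protein genes was 0.418 percentage points higher in microglia (exact permutation p = 0.036), and the cause was not tested. As medians over members, microglia levels turned from 94.2% to 104% of bulk brain for autophagy, from 132% to 82.6% for chaperone and from 62.7% to 231% for cell cycle genes, since the median gives each member equal weight. Of 45 named genes, Cask lost its call in 1 setting, without bulk brain replicate 1 (log2 difference 0.37). No pairing of same-numbered samples was detected (correlations of their deviations -0.021 to 0.010), which does not show that they came from different animals. The replicate block gave 6858 genes higher, 8037 lower, 5276 and 6870 at least 2-fold higher and lower, and 32 lists. Depth limits the folds of genes with few counts in a group, such as Kcnc1 with 2 in microglia. In the simulation, where few genes changed, 4.48% of 1.5-fold changes were recovered, which is not the recovery in the real comparison.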

Other observations

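The list tests were planned, while the tests of the synaptic and the immediate early pattern were chosen after the results were seen. Most innate immune genes were higher in the sorted cells. All 28 Toll-like receptor and inflammasome genes were higher in microglia (median log2 difference 5.98, camera adjusted p = 5.2e-15), with Tlr7, an endosomal RNA sensor, at 7.93 and Nlrp3 at 7.68. All 11 MHC class II genes (median 5.86, camera adjusted p = 8.9e-07) and all 14 MHC class I genes (median 4.29, adjusted p = 2.1e-07, and adjusted p = 0.091 with an estimated correlation) were higher. Of 26 chemokine and cytokine genes, 22 were higher (median 6.24, adjusted p = 2.4e-07). The 4 lower were Cx3cl1, Il34, Cxcl14 and Cxcl12, of which Cx3cl1 and Il34 encode ligands of the microglial receptors Cx3cr1 and Csf1r. Of 35 interferon-stimulated genes, 32 were higher (median 2.92, adjusted p = 1.0e-07, and adjusted p = 0.25 with an estimated correlation). Of 31 genes near Alzheimer risk loci, 21 were higher and 7 lower (median 2.87, adjusted p = 5.5e-06). Cd33 (7.49), Abi3 (7.26) and Inpp5d (7.13) were highest, and Mapt (-8.70), Clu (-7.00) and App (-2.61) were lower.

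Most glycolysis and respiratory chain genes were lower in the sorted cells. Of 22 glycolysis genes, 18 were lower (median -1.98, camera adjusted p = 0.013, and adjusted p = 0.40 with an estimated correlation), while the hexokinase genes Hk3 (7.16) and Hk2 (6.50) and the lactate transporter gene Slc16a3 (3.55) were higher. The glycolysis median was -1.80 against bulk brain replicates 3 to 5 alone and -2.38 against replicates 1 and 2 alone. Of 83 nuclear-encoded respiratory chain genes, 82 were lower (median -1.91, adjusted p = 6.6e-05, and adjusted p = 0.61 with an estimated correlation), and all 12 mitochondrially encoded genes tested were lower (median -2.23, adjusted p = 0.0021, and adjusted p = 0.081 with an estimated correlation). Summed respiratory chain transcripts stood at 12393 and 17342 CPM in bulk brain replicates 1 and 2 and at 7406 to 7708 CPM in replicates 3 to 5, and the list median was -2.55 against the former alone and -1.39 against the latter alone. Of 23 cholesterol genes, 18 were lower (median -1.59, adjusted p = 0.0096, lost against bulk brain replicates 3 to 5 alone), and the efflux pump gene Abca1 was higher (3.91). Of 18 V-ATPase genes, which encode the proton pump of lysosomes and synaptic vesicles, 13 were lower and 3 higher (median -0.96, adjusted p = 0.093), and the list passed the threshold without bulk brain replicate 3, 4 or 5 (adjusted p = 0.043 to 0.046), against replicates 3 to 5 alone (0.037) or 1 and 2 alone (0.0023) and with no low-count filter (0.016), but not with an estimated correlation (adjusted p = 0.55). The lower ones included Atp6v0e2 (-8.71) and Atp6v1g2 (-5.36). Of 28 cell cycle genes, 20 were higher (median 1.21, adjusted p = 0.0039, adjusted p = 0.052 with an estimated correlation and 0.17 against bulk brain replicates 3 to 5 alone), with Mki67 at 17.9 CPM against 1.91 CPM. Their summed level was lower, at 62.7% of bulk brain (exact permutation adjusted p = 0.0088), of which Stmn1 held 423 of 610 CPM in bulk brain and 16.6 CPM in microglia.

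Further cell classes of the brain or the blood were counted in the same way. All 16 inhibitory neuron genes (median -10.37, or -10.20 with zero-count genes at their bound, camera adjusted p = 1.4e-07), 15 of 15 excitatory neuron genes (-9.18, adjusted p = 1.7e-09) and 15 of 15 oligodendrocyte precursor genes (-8.43, adjusted p = 8.9e-07) were lower. All 13 mural genes (-4.07, adjusted p = 0.0039), all 11 fibroblast and meningeal genes (-5.86, adjusted p = 8.8e-05) and 13 of 14 ependymal and choroid plexus genes (-2.96, adjusted p = 0.017) were lower. With an estimated correlation the adjusted p of these last 3 lists was 0.090, 0.10 and 0.25, and the ependymal call was also lost without bulk brain replicate 2 (adjusted p = 0.13). Against bulk brain replicates 3 to 5 alone the mural (adjusted p = 0.17) and ependymal (0.47) calls were lost. Of 8 neutrophil genes, 7 were higher (3.72, adjusted p = 0.013, and adjusted p = 0.17 with an estimated correlation), of which Csf3r (985 CPM) is also expressed by microglia while S100a9 stood at 4.73 CPM. Of 8 monocyte genes 5 were higher (adjusted p = 0.13), with Ccr2 at 25.6 CPM, and of 6 T and NK cell genes 2 were higher and 4 lower (adjusted p = 0.74). Of 5 B cell genes, 4 were higher (6.26, adjusted p = 0.022, and adjusted p = 0.077 with an estimated correlation), with Ighm at 337 CPM against 20.3 CPM and Cd79b at 15.9 CPM. The B cell call was also lost when any single microglia replicate was left out (adjusted p = 0.060 to 0.082), with the replicate number as a block (0.058) and against bulk brain replicates 3 to 5 alone (0.059). Of 6 erythroid genes, 2 were lower and 4 did not pass the threshold (adjusted p = 0.54).

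Synaptic transcripts left in microglia were unevenly spread: of 133 synaptic genes, 45 lay above the 90th percentile of neuronal genes outside the synapse (1.03% of the bulk brain level), and 10 genes held 66.5% of their CPM. RNA carried over from neurons, which lack CD11b, in the proportions of the tissue would give 18.3% ± 6.07 (SD, n = 5 libraries) of the synaptic CPM in microglia, even at that percentile. This argues against such carry-over as the source of most of this RNA. Carried-over neuronal material richer in synaptic transcripts than the tissue was not tested and stays open. RNA carried over from non-neuronal cells was not tested and also stays open. As medians over members, microglia held endothelial genes at 19.7% of the bulk brain level, astrocyte genes at 0.425% and oligodendrocyte genes at 0.598%. For neuronal genes outside the synapse that median was 0.133%. Reads of overlapping genes are argued against as the main source, since 17.1% of the CPM of the 42 genes more than 10 times over the neuronal median lay in genes that overlap a gene of equal or higher microglial CPM (8 of 42 against 13 of 91 other synaptic genes, Fisher's exact test p = 0.61). For the 88 synaptic genes at or below the percentile, Snap25 and Syp among them, expression in microglia and carried-over RNA cannot be told apart, because their levels are those of other neuronal genes. For the genes above it, such as Cask, Stxbp5 and Ppp1r9b, transcription by the sorted cells may be the source. Counts alone do not settle this hypothesis, and carry-over from non-neuronal cells was not weighed against it.

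Immediate early and stress transcripts were higher in the sorted cells, with 35 of 36 genes past the threshold. Bulk brain held homeostatic microglia genes at a median of 0.883% and a lowest value of 0.533% of the microglial level. Below that lowest value lay 10 of 36 immediate early and dissociation genes, Ccl3, Atf3, Zfp36 and Hspa1b among them. This argues against the same level in tissue for these 10 (also 10 against bulk brain replicates 3 to 5 alone). The Fos, Jun and Egr genes of the list all lay above it, with Fos at 0.971%, Jun at 1.07% and Egr1 at 10.9%. For those genes the same level in tissue is not argued against. The median over 13 border-associated macrophage genes was 3.68% (two-sided permutation test against the homeostatic genes with 100000 resamples, p = 0.00038), and 0 lay below the lowest homeostatic value. Summed over the lists, however, microglia stood 49.7-fold over bulk brain for border-associated macrophage genes and 54.4-fold for homeostatic genes. Siglec1 lay at 0.788%. Ratios rise where other tissue cells hold the transcript, as for Colec12 (199%), so better recovery of border-associated macrophages is not settled. Transcription during cell isolation would give an excess of immediate early and dissociation genes below the lowest homeostatic ratio. The share was 30.3% of 33, against 3.34% of 1196 other coding genes of at least 18.8 CPM in microglia (Fisher's exact test p = 2.3e-07). Genes above the highest homeostatic ratio (21.5%) were left out of both. Levels were not otherwise matched, and homeostatic genes, which cannot lie below, were not taken out of the 1196. The test treats genes as independent, though the list's estimated inter-gene correlation was 0.24, so its p-value does not measure the spread between samples. Better recovery of other myeloid cells stays open (of neutrophil list genes, S100a9 lay at 2.36%, and Csf3r, which microglia also express, at 0.485%), as does the source of the other immediate early genes, and Hspa1a and Hspa1b may share reads.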
